A study of Oryza sativa with 6 samples.

How the data were processed

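Small RNA libraries from rice shoots were made by the submitters from total RNA with a small RNA kit and sequenced single-end on an Illumina instrument, per the labels' protocols. FastQC 0.10.1, Bowtie and StringTie 1.3.0 are named per the submitters' processing notes, with no role given. The aligner settings, the genome build and the release of the miRNA reference are not given in the sources used here, so no coordinates are printed. The deposited workbook held 3 sheets: all 562 entries, the same table without 1 entry (561), and 40 miRNAs that the authors listed as changed. Each entry had a name, a sequence, an estimated count per library in the columns the authors marked raw, and a normalized signal per library, per the file headers. The deposited estimated counts were whole for most entries, and 10.5% to 18.1% of the 562 values of a library were not whole, to a tolerance of 0.001. Where a sequence stood under more than 1 name (21 sequences), the deposited counts were equal under each. Of their 100 library values above 0, 60 were not whole under a single name, and 31 of those were whole when summed over the names, to the same tolerance. Division of reads over the names would give this for those 31, and it is not settled for the rest. Among sequences under 1 name, 16.1% of the values above 0 were also not whole, which division over listed names cannot give. Families were also tested with each sequence counted once. The normalized signal deposited by the authors was the count multiplied by 1 factor per library. The authors also deposited a fold change (a ratio of group means), its log2, and a p-value per entry. These were used only to describe the authors' deposited table.

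Small deposited counts were rare. Among sequences with a whole count (tolerance 0.001), 50 values lay between 1 and 5 and 106 were exactly 6, so the table appears to leave out most values under 6, by a rule not given in the sources used here. A listed 0 (23.5% of values) can therefore stand for several reads, and in control replicate 3 a count of 6 is worth 39.2 CPM, against 4.13 in cadmium replicate 3 (scaled by TMM). No upper limit or fold is drawn from a 0 for that reason, a departure from the 3-count limit usual for a full count table.

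Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr at its defaults (minimum count 10, minimum total 15), robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. Of the 562 entries 207 were left out by the filter, and 355 were tested, holding at least 99.6% of each library's counts. Family values came from the same test on counts summed over all entries whose name carries the same miRNA number (144 families, 112 tested). Entries of both arms of a precursor were summed together. The SE of a log2 fold change was its absolute value divided by the square root of the quasi-likelihood F statistic. CPM values were scaled by TMM. Members of a family share much of their sequence, so single entries of one family are uncertain where reads could fit several. The lists fixed before the data were examined (SPL, copper, auxin, nutrient, leaf growth, miRNA pathway, miR444, miR1432, reproductive phased small RNA triggers, resistance-gene initiators, transposable-element hairpins, and families with functional work in cadmium-exposed rice) were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated one. Of 55 listed families 35 were in the table, 31 were tested, and miR444, miR2275, miR482 and miR814 had too few counts. Shares of counts were compared by two-sided exact permutation tests, whose smallest p is 0.1 for 3 against 3.

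The rule for named entries was also fixed before the data were examined. It took up to 12 higher and 12 lower entries with the largest log2 fold change among those with an adjusted p under 0.05, a mean of at least 10 counts in the higher group and no overlap between the groups. Sequences that were the same or trimmed forms of one another were named once, by the more abundant. The rule also took the sum of each detected family of the lists and the 5 most abundant entries. It gave 12 higher and 7 lower entries. Entries named outside it are said to be so.

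The alternatives were relative log expression factors, total counts, DESeq2 1.42.0, limma on log2 of the authors' normalized signal plus 1 or plus 10, no filter, rice entries only, the most abundant entry of each family, camera on ranks, length shares without the most abundant entry or without predicted candidates, a replicate block, and each library left out in turn. Added after seeing the data were 1 entry per sequence, each sequence counted once in its family, libraries thinned to the shallowest, the copper entries left out, and entries with a mean of at least 200 CPM. For 1 entry per sequence the counts were summed over the names, which repeats reads if these were not divided. Where each sequence was counted once in its family, the count under 1 name was kept, which leaves out reads if these were divided. The replicates of the groups share only a number. Plots were drawn with matplotlib 3.10.9.

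The tests were tested on simulated data with the real means, depths and spread and 200 changed entries. The 200 were drawn from all 562 entries, of which 361 passed the filter. Among the changed entries that passed it, edgeR recovered 27.6% of 4-fold and 94.0% of 12-fold changes. Changed entries that the filter removed were not counted as missed, so recovery over all changed entries was lower. Of its calls 2.47% were unchanged entries, and it made 0 calls with nothing changed. For families (103 passed the filter) it recovered 33.3% of 4-fold and 84.6% of 10-fold changes, again among those that passed. Of its calls 5.88% were unchanged families. The simulated entries varied independently of one another, and small counts were not removed. More entries changed (200) than the 32 called in the real data, in equal numbers up and down. These rates therefore hold for the simulation only, in which most 4-fold changes were missed.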

Results

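Small RNA libraries were sequenced from shoots of hydroponically grown rice seedlings of an indica cultivar described as accumulating little cadmium in the grain. Cadmium chloride was given at 0 µM (control, 3 libraries) or 100 µM (3 libraries) for 12 days, starting at the 1-leaf stage. The deposited table listed 562 small RNA entries with a count in each library: 365 named after rice miRNAs, 88 after miRNAs of other plants and 109 predicted candidates. In the entry names, L and R codes give bases trimmed from or added to the ends of the reference sequence, "ss" a substitution, and p5 and p3 the arms of a precursor. The total counts were 503744, 654888 and 106834 in control replicates 1 to 3, and 344793, 471875 and 1529101 in cadmium replicates 1 to 3, a 14.3-fold range. Control replicate 3, the shallowest library, stood apart from the other controls, with a Spearman correlation across entries of 0.841 with control replicate 1 and 0.812 with control replicate 2, against 0.962 between those. Cadmium replicate 1 correlated better with control replicates 1 and 2 (0.872 and 0.861) than with cadmium replicate 2 (0.858), and at 0.926 with cadmium replicate 3. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

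The first comparison asked which miRNA families differed in the shoot between 100 µM and 0 µM cadmium. The 4 families of the copper list, whose targets encode copper proteins, rose 9.02-fold to 10.8-fold in cadmium. Each family value sums the listed entries of both arms, and the target named for a family was not assigned to an arm here. Of the miR397 counts, the 3p-arm entry osa-MIR397b-p3 held 3409 of 6127 in control replicate 1 and 97014 of 178270 in cadmium replicate 3. miR397, which targets laccases, went from 13483 ± 5630 to 121531 ± 6474 CPM (read counts scaled to a common library size, mean ± SD, n = 3 per group). miR398, which targets copper/zinc superoxide dismutases, went from 1173 ± 380 to 12023 ± 3523, miR408, which targets plantacyanins and laccases, from 5226 ± 3046 to 51113 ± 10295, and miR528, which targets ascorbate oxidase in rice, from 5396 ± 4582 to 58440 ± 5221. The value of miR528 rested in part on control replicate 3: without it the log2 fold change was 4.21 in place of 3.44. miR164, which targets NAC transcription factors, fell by 1.89 on the log2 scale, from 26760 ± 7874 to 7236 ± 796 CPM. Each cadmium library lay beyond every control library in these 5 families, a separation that chance gives 10% of the time with 3 against 3. It is no mark of these 5, as families that did not pass also had it, such as miR319 and miR160 (edgeR adjusted p = 0.511 for each).

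With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 112 families, the log2 fold changes (± SE) were 3.17 ± 0.38 for miR397 and 3.36 ± 0.42 for miR398, both at an adjusted p of 0.00111. They were 3.29 ± 0.48 for miR408 (adjusted p = 0.00244), 3.44 ± 0.60 for miR528 (adjusted p = 0.00688) and -1.89 ± 0.34 for miR164 (adjusted p = 0.00688). These 5 were the families that passed, and 16 had an unadjusted p under 0.05. Among the 31 tested families of the fixed lists, 8 passed when adjusted over the list alone, 6 higher and 2 lower. The additional ones were miR1432, which targets a calcium-binding protein (1.24 ± 0.36, adjusted p over the list alone 0.0316), miR810 (1.51 ± 0.48, 0.0461) and miR172, which targets AP2-type factors (-1.15 ± 0.33, 0.0316). Over all families their adjusted p-values were 0.0998, 0.117 and 0.0979. The call of miR164 was lost without control replicate 1 (-1.42, adjusted p = 0.0624), the highest adjusted p among its 17 alternatives. The count of families was 8 with total counts as the scale, 13 with DESeq2, 9 without control replicate 3 and 10 without cadmium replicate 1.

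The other families of the fixed lists did not pass over all families, and their log2 fold changes are given as values. Among regulators of leaf growth and patterning, miR171, which targets GRAS factors, had -0.90 ± 0.31 and miR319, which targets TCP factors, 0.70 ± 0.42. miR396 (-0.29), miR166 (-0.12), miR159 (-0.06) and miR394 (0.14) lay within 1 SE of 0. In the miRNA pathway, miR162, which targets DCL1, had -1.08 ± 0.42 and miR168, which targets AGO1, 0.04 ± 0.29. Most miR168 counts were of the 3p-arm entry osa-miR168a-3p_L-3, with 86042 of 110324 in control replicate 1 and 184012 of 220566 in cadmium replicate 3. The auxin-related families miR160, miR167, miR390 and miR393 had -0.49, -0.40, -0.26 and -0.21. The regulators of SPL factors, miR156, miR529 and miR535, had 0.15, 0.34 and -0.28. Of the nutrient families, miR395, a regulator of sulfate assimilation, had 0.53 ± 1.26, the phosphate-related miR399 and miR827 had -1.29 ± 1.23 and -0.78 ± 0.43, and miR169, which targets NF-YA factors, had -0.34 ± 0.29. miR2118, a trigger of phased small RNAs in reproductive tissue, had 0.64 ± 0.68. The hairpin families miR812, miR820 and miR1862 had 0.53, 0.95 and 1.02. miR156, miR168 and miR394 changed sign under another scaling or tool, as did miR399.

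Some of these families passed over all families in a single alternative. miR171 did with total counts (-1.21, adjusted p = 0.0331), miR162 with DESeq2 (-1.24, 0.0496), miR399 without control replicate 3 (-2.05, 0.0468), miR1862 without cadmium replicate 1 (1.74, 0.0458) and miR1432 without control replicate 1 (1.83, 0.0168). The highest adjusted p over the 17 alternatives was 0.681, 0.586, 0.989, 0.863 and 0.343 for these families. miR172 passed in 3 of 17, with total counts, with DESeq2 and without control replicate 3 (adjusted p = 0.0226, 0.0215 and 0.0231, with 0.505 as the highest).

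**Figure D1:**
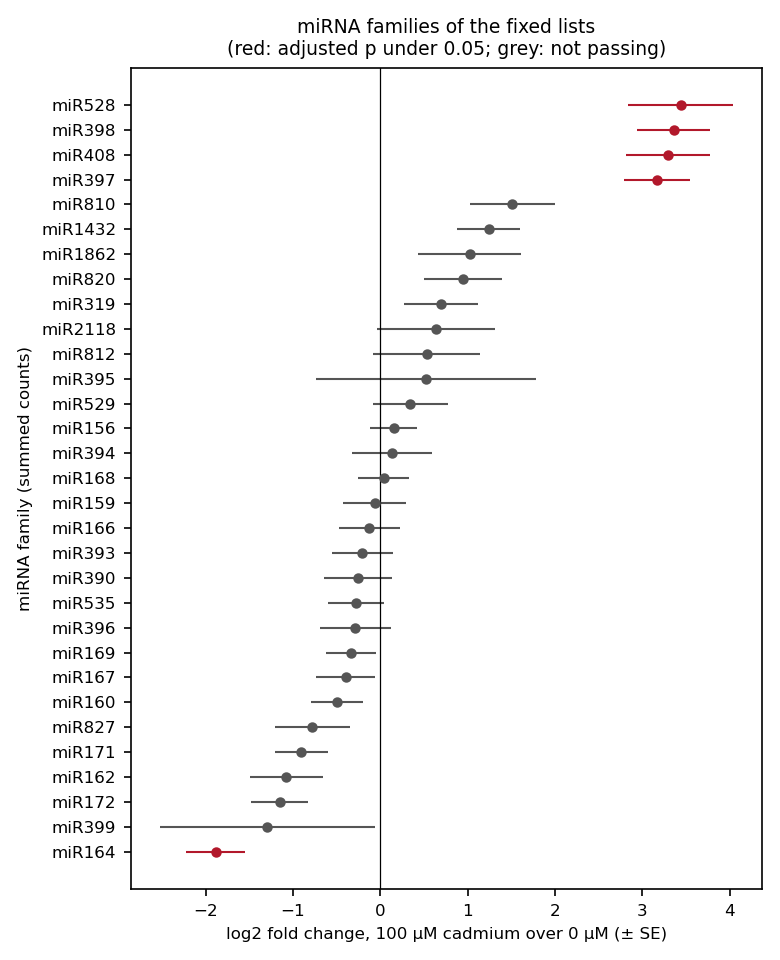
Log2 fold change (x axis, 100 µM over 0 µM cadmium) of the summed counts of each tested miRNA family of the fixed lists (y axis). Points give the edgeR estimate and bars ± 1 SE, derived from the quasi-likelihood F statistic (3 libraries per group). The 4 copper families lie between 3.17 and 3.44 and miR164 at -1.89, and these 5 are in red for an adjusted p under 0.05; miR156, miR168, miR394 and miR399 change sign under another scaling or tool.

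The second comparison took each small RNA entry by itself. Of 355 entries tested, 32 passed, 20 higher and 12 lower, which is 28 distinct sequences, and 79 had an unadjusted p under 0.05. Among the higher entries, 15 were of the copper families. osa-miR408-5p_L+1R-1 had a log2 fold change of 4.71 ± 0.88, osa-miR528-3p 4.02 ± 0.66, osa-MIR398b-p5 3.99 ± 0.89, osa-miR398b 3.77 ± 0.39, osa-miR528-5p 3.58 ± 0.53, osa-MIR397b-p5 3.52 ± 0.30, osa-miR408-3p 3.39 ± 0.40 and osa-MIR397b-p3 3.13 ± 0.34. The most abundant form of miR528, TGGAAGGGGCATGCAGAGGAG, went from 4460 ± 3292 to 53072 ± 7153 CPM (SD, n = 3). mtr-miR397-5p_L-2R+3 was listed at 0 in all 3 controls and at 34, 46 and 132 counts in cadmium replicates 1 to 3 (adjusted p = 0.0127, edgeR). A listed 0 can stand for several reads in this table, so no fold is given for it. Without control replicate 3 the log2 fold change was 6.16 for osa-miR408-5p_L+1R-1, 4.89 for osa-miR528-3p and 4.27 for osa-miR528-5p, and without control replicate 2 that of osa-miR408-5p_L+1R-1 was 4.07. osa-MIR398b-p5 had 180 counts in cadmium replicate 2, against 1055 in cadmium replicate 1. Without cadmium replicate 1 its log2 fold change was 2.96 (adjusted p = 0.0946, the highest of 17 alternatives), and it passed in 12 of those. The calls of osa-miR408-5p_L+1R-1 and osa-miR528-3p were also lost without cadmium replicate 1 (adjusted p = 0.0630 and 0.0521, the highest for each), and mtr-miR397-5p_L-2R+3 passed in 9 of 14 alternatives.

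The 5 higher entries outside the copper list came from other families. osa-MIR167j-p3, the 3p arm of a miR167 precursor, rose 14.01-fold, from 96.5 ± 41.1 to 1320 ± 180 CPM (log2 3.81 ± 0.45, adjusted p = 0.00145, edgeR), while the sum of its family had a log2 value of -0.40. osa-miR529b, of a family that targets SPL factors, had a log2 fold change of 2.03 ± 0.50 and osa-miR2877_1ss16TA 2.03 ± 0.50 (both at an adjusted p of 0.0432). osa-miR1432-5p_R+1 (1.33 ± 0.32) and osa-miR156f-3p (1.10 ± 0.29) also passed, and are named after their values were seen. osa-miR529b and osa-miR2877_1ss16TA no longer passed with relative log expression factors (adjusted p = 0.0593 and 0.0578), and the highest adjusted p over their 18 alternatives was 0.238 (without control replicate 1) and 0.254 (without cadmium replicate 2, where the log2 fold change of osa-miR2877_1ss16TA was 1.39).

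**Figure D2:**
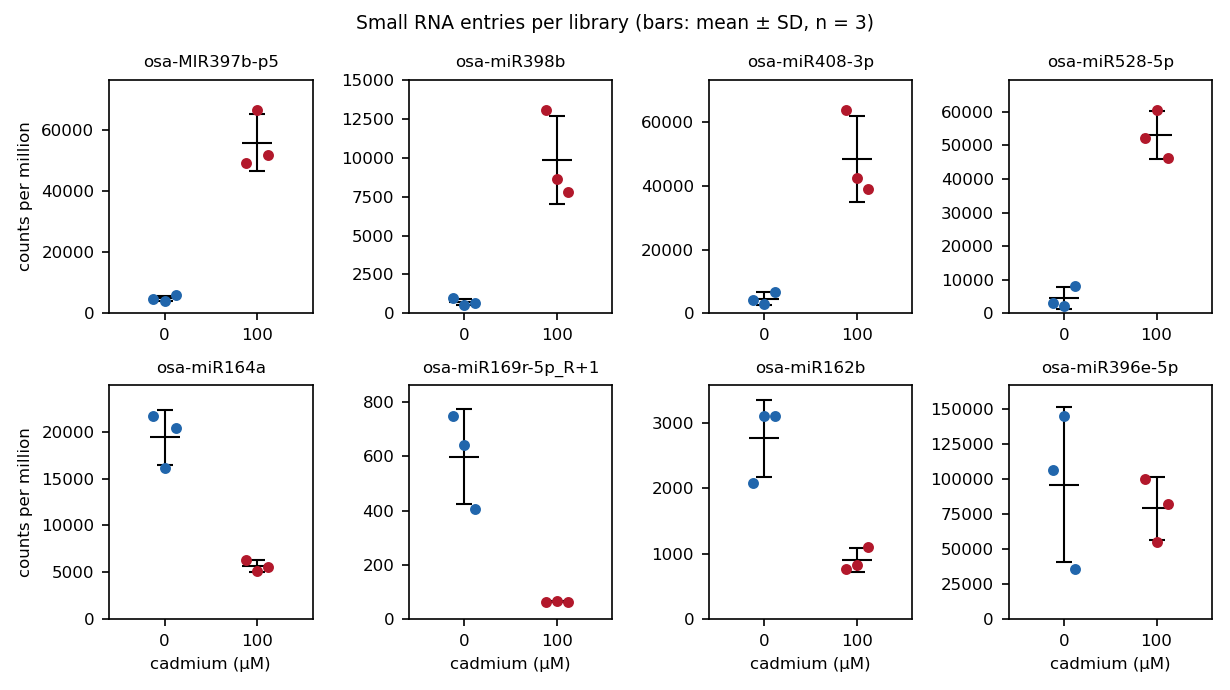
CPM (y axis, scaled by TMM) of 8 small RNA entries in each library at 0 or 100 µM cadmium (x axis), with points for libraries and bars for the mean ± SD (n = 3). The forms of miR397, miR398, miR408 and miR528 lie higher in every cadmium library, those of miR164, miR169 and miR162 lower, and osa-miR396e-5p overlaps between the groups.

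The 12 lower entries held 7 of miR169 (3 distinct sequences), 3 of miR164, osa-miR162b and osa-miR530-5p_R+1, the last named after its values were seen, as its groups overlapped. osa-miR169r-5p_R+1 fell by 3.22 on the log2 scale, from 599 ± 176 to 64.4 ± 2.23 CPM (SE 0.43, adjusted p = 0.00285, edgeR, n = 3 per group). The opposite arm, osa-miR169r-3p, had -2.63 ± 0.58, and osa-MIR169g-p3, a 19-nt sequence listed with equal counts under 5 precursors, had -1.87 ± 0.47. Of the 26 tested miR169 entries, 7 passed. The miR164 entries were osa-MIR164d-p3 (-2.50 ± 0.60), osa-miR164d (-2.22 ± 0.37) and osa-miR164a (-1.78 ± 0.27), the last going from 19399 ± 2924 to 5660 ± 600 CPM. osa-miR162b, of the family that targets DCL1, had -1.61 ± 0.36. Among 18 alternatives osa-miR169r-5p_R+1 and osa-miR164a passed in 18, osa-miR164d in 16 (lost without cadmium replicate 1 or 3), osa-miR169r-3p in 13, and osa-MIR164d-p3, osa-MIR169g-p3 and osa-miR162b in 11. The last 4 each lost their call without control replicate 1 and without each of the cadmium replicates. Of the 5 most abundant entries, osa-MIR397b-p3 passed, and osa-miR168a-3p_L-3 (0.16 ± 0.25), osa-miR396e-5p (-0.28 ± 0.48), osa-miR1425-5p (0.61 ± 0.51) and osa-miR156a_L+1 (0.22 ± 0.27) did not. With edgeR, 0 of the 48 tested predicted candidates passed, and 4 had an unadjusted p under 0.05.

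The median log2 fold change over all tested entries was 0.18 with TMM scaling, 0.04 with relative log expression factors and -0.16 with total counts, where 14 entries were higher and 17 lower. Calls numbered 55 with DESeq2, 16 without control replicate 1, 22 without control replicate 2, 47 without control replicate 3, and 10, 18 and 13 without cadmium replicates 1, 2 and 3. With the copper entries left out before scaling, a check chosen after seeing the data, 4 of the other 17 calls passed (osa-MIR167j-p3, osa-miR169r-5p_R+1, osa-miR164a and osa-miR164d).

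The lists of families fixed before the data were examined were then tested as groups of entries with camera. In the copper list 15 of 17 tested entries were higher, with the same count when adjusted over the list alone, and 2 did not pass, osa-miR398a (0.36 ± 0.42, adjusted p = 0.706) and osa-MIR398a-p5 (0.10 ± 0.97, adjusted p = 0.982), named after their values were seen. Its camera adjusted p was 5.13e-26 with the preset correlation of 0.01, and the adjusted p was 0.0885 with an estimated correlation, which was 0.391. Other splits of the 6 libraries into groups of 3 were a check chosen after seeing the data. In these its unadjusted camera p with the preset correlation was 5.46e-10 to 0.413, against 5.13e-27 in the real split. A small p at that setting therefore did not need the real groups, though such splits still held unequal numbers of cadmium libraries per side. The 17 are distinct sequences, but some differ only at the ends, as osa-miR398b, bdi-miR398a_R+1 and bdi-miR398a_R+3 do. Some of the 15 were listed at 0 in every control. End variants are not independent of one another, so the 15 are not separate results. In the nutrient list 7 of 31 entries were lower, all of them miR169, and 7 when adjusted over the list alone. Its camera adjusted p was 9.75e-07, and the adjusted p was 0.517 with an estimated correlation. Of the 31 entries 26 were of miR169, so the list was mostly a test of that family. Among the 31, 28 had a log2 value below 0 and 3 above, such as osa-MIR169a-p5 (0.61 ± 0.30), which did not pass. Apart from osa-miR169r-5p_R+1, the 7 lower entries were of 3p arms. The NF-YA factors named as targets of miR169 were not assigned to an arm here. These 7 are 3 distinct sequences, and the 31 are 24; with 1 entry per sequence, a check chosen after seeing the data, the adjusted p was 0.000758. In the leaf growth list 3 of 62 entries were lower, all of them miR164, and 2 when adjusted over the list alone (adjusted p = 0.00272, and adjusted p = 0.517 with an estimated correlation). The call of the leaf growth list was lost without cadmium replicate 2 (adjusted p = 0.114), and none of the 3 list calls held with an estimated correlation.

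The other 7 tested lists did not pass. Of the SPL list, 2 of 29 entries were higher, osa-miR529b and osa-miR156f-3p, and 3 when adjusted over the list alone (camera adjusted p = 0.43). Here osa-miR156f-3p is of a 3p arm, as is osa-MIR167j-p3, the entry of the auxin list that passed. The auxin list had 1 of 24 higher (osa-MIR167j-p3) and 1 when adjusted over the list alone (0.712), the miRNA pathway list 1 of 7 lower (osa-miR162b) and 1 over the list alone (0.326), and miR1432 1 of 2 higher and 1 over the list alone (0.326). Among entries of transposable-element hairpins, 0 of 13 passed with edgeR or over the list alone, and all 13, which are 11 distinct sequences, had a log2 value above 0 (camera adjusted p = 0.0750). This list passed with camera on ranks (adjusted p = 0.00174) and without cadmium replicate 1 (0.00210), and not in the other alternatives, among them 1 entry per sequence (0.185), with 0.615, the highest, as the adjusted p with an estimated correlation. 0 of 4 entries of the reproductive phased small RNA triggers passed (0.961), and 0 of 18 of the list drawn from functional work on cadmium-exposed rice, here miR166 and miR390 (0.712). miR444 and the list of resistance-gene initiators had too few counts to be tested.

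The share of counts taken by the copper families was 2.11% (exact 95% binomial interval 2.07 to 2.15), 1.57% (1.54 to 1.602) and 4.85% (4.72 to 4.98) in control replicates 1 to 3. In cadmium replicates 1 to 3 it was 21.5% (21.4 to 21.6), 22.8% (22.7 to 22.9) and 21.7% (21.6 to 21.7), and these intervals cover counting error only. The group means were 2.84% ± 1.76 and 21.98% ± 0.686 (SD, n = 3), with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows.

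The last comparison took the length of the small RNAs, since Dicer-like enzymes differ in the lengths they make. Sequences of 22 nt, the length of the main miR397 forms, held 10.6% ± 3.79 of control counts and 18.6% ± 2.53 of cadmium counts (SD, n = 3; two-sided exact permutation p = 0.1, adjusted over 5 lengths 0.5). Without the copper entries these shares were 9.51% and 10.3%. The 21-nt share was 78.9% ± 5.32 and 72.2% ± 3.12, the 20-nt share 4.39% and 3.75%, the 23-nt share 0.587% and 0.605%, and the 24-nt share 2.67% ± 1.63 and 3.69% ± 2.00. No length class could pass an adjusted 0.05 in a design of this size.

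The authors' deposited table gave a p-value for each entry and listed 40 miRNAs as changed, 26 up and 14 down. Of the entries in the authors' deposited table, 41 had a p-value of 0.05 or less, and after Benjamini-Hochberg adjustment here the smallest was 0.136. Of the 40 entries in the authors' deposited table of changed miRNAs, 38 were tested here and 19 passed, and 13 entries that passed here were not on it.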

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

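Copper entries left out, libraries thinned, 1 entry per sequence, each sequence counted once in its family and the 200 CPM minimum were chosen after seeing the data, as were the tests of other splits. The families miR397, miR398, miR408 and miR528 kept their direction and passed in all 17 alternatives run for them. Entry calls (32: 20 higher, 12 lower) numbered 55 with DESeq2 (31 and 24), 4 without copper entries (1 and 3; fewer small p-values entered the adjustment and fold changes barely moved), 32 at the 200 CPM minimum, and 10 to 47 with 1 library left out (8 to 24 higher, 2 to 23 lower). Of the named entries, osa-MIR167j-p3, osa-miR398b, osa-miR528-5p, osa-MIR397b-p5, osa-miR408-3p, osa-MIR397b-p3, osa-miR169r-5p_R+1 and osa-miR164a passed in each alternative that tested them, and each of the others lost its call in at least 1; osa-miR529b passed in 6 of 18 and osa-miR2877_1ss16TA in 5 of 18. Summed by family, 5 passed. Family calls (5: 4 higher, 1 lower) were 8 with total counts (4 lower), 13 with DESeq2 (7 and 6), and 5 to 10 with 1 library left out (4 to 8 and 1 to 5). The lower ones were 2 with relative log expression factors, no filter, the most abundant entry, rice entries only or thinned libraries. List calls (3) numbered 0 with an estimated correlation, 4 with ranks, 4 without cadmium replicate 1, 2 without cadmium replicate 2, and 3 in each other alternative. The cause of these shifts was otherwise not tested. Depth limits the small values: a count of 6 is 39.2 CPM (scaled by TMM) in control replicate 3.

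The replicates share only a number: deviations of same-numbered libraries correlated at 0.12, -0.228 and -0.0454, and not every library correlated best with its own number. With a replicate block, 15 entries (11 higher, 4 lower) and 7 families (3 lower) passed. Under the block family miR394 had -0.037 and the list of reproductive triggers an adjusted p of 0.994 in the other direction.

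Other results that changed direction did not pass in any setting that reversed them, and the cause was not tested. With total counts osa-miR168a-3p_L-3 had -0.19, osa-miR156a_L+1 -0.13, and families miR156, miR394 and miR168 -0.12, -0.19 and -0.22. With relative log expression factors miR156 and miR168 had -0.0057 and -0.11, and with DESeq2 -0.0062 and -0.11. With limma at pseudocounts 1 and 10 osa-miR168a-3p_L-3 had -0.00872 and -0.00872, miR168 -0.034 and -0.034, and miR394 -0.16 and -0.15. At pseudocount 1 miR399 had 0.24. By the most abundant entry miR529 had -0.24, miR395 -1.23, miR169 0.51 and miR166 0.060. With rice entries miR156 had -0.0499, miR159 0.047 and miR168 -0.084. Thinned, miR159 had 0.098. With each sequence counted once miR395 had -0.12 and miR159 0.10, and 5 families passed. With 1 entry per sequence the reproductive triggers had an adjusted p of 0.975. Without the copper entries the 20-nt difference was 0.277 percentage points. With 1 library left out, the ranges were -0.13 to 0.31 (osa-miR168a-3p_L-3), -0.048 to 0.34 (osa-miR156a_L+1), -0.042 to 0.57 (miR156), -0.010 to 0.74 (miR529), -0.50 to 0.10 (miR535), -0.60 to 0.26 (miR390), -0.64 to 0.19 (miR393), -0.14 to 2.33 (miR395), -0.49 to 0.51 (miR166), -0.35 to 0.36 (miR159), -0.26 to 0.66 (miR394), -0.21 to 0.53 (miR168) and -0.54 to 1.21 (miR2118). They were -1.36 to 0.0446 and -0.0370 to 0.125 percentage points for the 20-nt and 23-nt differences, and adjusted p-values of 0.564 to 0.839 (list SPL) and 0.668 to 0.964 (reproductive triggers).

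Of the 10 splits of the 6 libraries into groups of 3, 1, the real one, gave as many entries (32, highest other 0), and 1 gave as many families (5, highest other 0). Entries with an unadjusted edgeR p under 0.05 numbered 79 in the real split. They numbered 59 with control replicates 1 and 2 and cadmium replicate 1 set against the rest, and 2 to 11 in the remaining splits. For lists, 3 splits gave at least the real 3, and the highest other was 4. A share under 0.05 cannot be reached with 10 splits.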

Other observations

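In this part the counts of 24-nt entries, the correlation between hairpin arms, the comparisons made of the copper families with 3 technical explanations and the Poisson probability were chosen after the results were seen, while the fits, the shares by length, the other scalings and the run without control replicate 3 were planned. Families outside the fixed lists held further values. miR530 had the most negative family value, a log2 fold change of -4.38 ± 1.09 (edgeR adjusted p = 0.0529), and both arms of its hairpin went the same way: osa-miR530-5p_R+1 at -4.40 ± 1.08 passed (adjusted p = 0.0432) and osa-miR530-3p had -4.06. The counts of osa-miR530-5p_R+1 were 1789, 1843 and 28 in control replicates 1 to 3 and 14, 89 and 76 in cadmium replicates 1 to 3, so control replicate 3 stood far below the other controls. miR5794 (-1.10 ± 0.34), miR2122 (1.53 ± 0.52), miR2877 (2.00 ± 0.65) and miR5083 (-1.85 ± 0.76) had an unadjusted p under 0.05 and did not pass. The same held for miR5808, which was listed at 0 in every control, so no fold is given. Among 72 tested entries of 24 nt, 3 were higher, 0 were lower (edgeR, with 12 at an unadjusted p under 0.05) and 63 had a log2 value above 0. Over all 355 tested entries 20 were higher and 12 lower, 79 had an unadjusted p under 0.05, and the median log2 fold change was 0.18. The share above 0 over all entries was not taken. The 63 are not separate results, as some share a sequence, such as osa-MIR820a-p3 and osa-MIR820b-p3. Some signs rest in part on a listed 0, as for osa-MIR5542-p3_1ss17AG (6, 16 and 0 counts in control replicates 1 to 3). The 3 higher ones of 24 nt were osa-miR2877_1ss16TA, which passed in 5 of 18 alternatives, and bdi-miR398a_R+3 and bdi-miR397b-5p_L-1R+4. The last 2 are variants of copper families listed at 0 in every control. The 24-nt share of counts did not follow the groups, at 1.95%, 1.53% and 4.54% in control replicates 1 to 3 and 1.497%, 5.40% and 4.18% in cadmium replicates 1 to 3.

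The arms of a hairpin had correlated values outside the copper families, which may come from differences between libraries without any effect of cadmium. Across 33 other hairpins with a tested entry named for each arm, the log2 fold changes of the 5p and 3p entries had a Spearman rho of 0.712. Hairpins with an arm not marked in the entry name, such as that of osa-miR164d, were left out. The other 9 ways to split the 6 libraries into groups of 3 gave 0.191 to 0.592, with a median of 0.471. The same sign was seen in 24 of 33, against 20 to 26 in the other splits. With 10 splits the real one cannot come under a share of 0.1, so the tables cannot tell a change shared by both arms with cadmium from library differences.

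The rise of miR397, miR398, miR408 and miR528 was set against 3 technical explanations. The smallest log2 fold change of the 4 families over 3 other scalings was 2.87. These were relative log expression factors, total counts, and limma on the authors' normalized signal, which is also another test. The TMM factors ran only from 0.785 (cadmium replicate 1) to 1.43 (control replicate 3), so leaving them out could not have removed the rise. The choice among these scalings is thus not the whole cause, but a larger scale error was not tested. Without the shallow control replicate 3 the smallest was 3.33. That library had the highest copper share of the controls (4.85%), so leaving it out was bound to widen the difference and was no test. The tables argue against stabilisation of 1 arm only, for MIR397b, MIR398b, MIR408 and MIR528. These are the 4 of 5 hairpins with both arms tested in which an arm passed. The smallest log2 fold change among their 8 arm entries was 3.13 ± 0.34. Even so, the log2 ratio of 5p to 3p rose by 1.87 for miR408 (two-sided exact permutation p = 0.1, the smallest possible for n = 3, and 0.5 adjusted over the 5 hairpins). The size of that rise depends on control replicate 3, where the 5p and 3p counts were 59 and 1035. They were 36 and 2114 in control replicate 1 and 24 and 1910 in control replicate 2, ratios farther from those in cadmium. In the fifth hairpin, MIR398a, neither arm passed, with 0.10 ± 0.97 for osa-MIR398a-p5 and 0.36 ± 0.42 for osa-miR398a. A response to cadmium stays open as a hypothesis, for which no further test was run here.

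Variant forms of the copper families were listed at 0 in every control library, 7 in all, among them bdi-miR398a_R+1 at 47, 92 and 244 counts in cadmium replicates 1 to 3. A candidate explanation is the apparent minimum of 6 counts together with few reads of the parent form. At the ratio of variant to parent pooled over the cadmium libraries, where cadmium replicate 3 weighs most, 4 of the 21 control values would have been 6 or more. The joint Poisson probability that all stayed under 6 was then 4.61e-05. At the lowest ratio among the cadmium libraries it was 0.0487, with no expected count above 6.55. The 7 variants were picked because they stood at 0 in every control, so both probabilities are biased low and decide nothing. They also leave out the spread between libraries, and the second rests on values near the minimum. A lower ratio in controls and the minimum therefore cannot be told apart.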
